A study of Homo sapiens with 6 samples.

How the data were processed

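Total RNA (100 ng) from 6 groups of cultured cells was labelled and hybridised to Affymetrix whole-transcript arrays, per the labels' protocols. The groups were HCT116 and HCT116-p53KO cells with control or NRF3 siRNA, collected 48 h after transfection, and H1299 cells stably expressing GFP or NRF3. Each group had 1 array. The sequence and number of the siRNAs are not given in the sources used here.

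The deposited values are log2 intensities of 33297 probe sets, made with RMA in Affymetrix Expression Console, per the submitters' processing notes, with no version named. RMA corrects background, quantile-normalizes arrays and summarises probes, and which arrays were normalized together is not given in the sources used here. Median intensities were 6.98, 7.00, 6.99 and 6.95 on the HCT116 and HCT116-p53KO arrays and 6.08 and 6.05 on the H1299 arrays. Sorted values differed on average by 0.0157 to 0.0703 among the 4 HCT116-family arrays, by 0.0326 between the H1299 arrays and by 0.779 to 0.805 across these sets. Levels were therefore compared only within a line or between the HCT116 lines. The share of genes at a log2 intensity of 6 or more was 72.6% to 75.2% on the HCT116-family arrays and 58.7% to 59.8% on the H1299 arrays. No pair of arrays held the same values, with at most 2.36% of probe sets identical.

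Probe sets were named through the array's annotation table: 19460 had 1 gene symbol, 1754 had several and 12083 were not listed there and stayed unnamed. Entrez numbers of 19429 matched the RefSeq gene table of GRCh38.p14, which changed 0 symbols and was used for names and for which genes neighbour or overlap each other. Only probe sets with 1 symbol entered comparisons of genes, with the probe set of the highest mean for the 769 genes that had several, giving 18417 genes. The gene knocked out in HCT116-p53KO, whose own level had been planned as a check of labels, is not analysed here, and the list of p53 targets serves in its place. Some planned list members are likewise not analysed here.

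For each comparison the difference of log2 values was taken for genes at 6 or more on at least 1 of the 2 arrays. Genes were counted by size, at 2-fold, since 1 array per group allows no test. For 27 gene lists the median difference was placed among those of 10000 random lists of equal size matched on mean expression in 10 bins, where at least 5 members were measured. This percentile describes the arrays compared and is no test of the condition.

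limma 3.58.1 in R 4.3.3 was fitted with cell line as a block to the 4 HCT116-family arrays (NRF3 siRNA effect) and to all 6 arrays (more NRF3 minus less), with Benjamini-Hochberg adjustment at 0.05 and two-sided p-values. The only replication is across lines, so these p-values measure the spread of the effect between lines. For the 4 arrays this left 1 residual degree of freedom, and limma estimated a spread common to all genes, an SE of 0.16 for each. For all 6 arrays there were 2 residual degrees of freedom and a prior worth 5.90. Pearson and Spearman correlations were taken across genes, and genes at 1.5-fold or more in the same direction were counted beside the number expected for independent lists. The comparisons correlated share no arrays.

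The 27 lists, the rule for named genes, the comparisons, most tests and most alternatives were fixed before the data were examined. A list of YAP and TAZ targets and some tests of explanations were added afterwards. The rule named NFE2L3, the 10 largest differences each way per NRF3 comparison (5 each way for HCT116-p53KO against HCT116), the 10 most shared each way by both knockdowns, the 5 most shared each way by all 3 comparisons, the genes called by limma up to 10 each way, and up to 4 members of each list with the largest differences. Small RNAs, recognised by symbol, were counted and not named, and the pattern used also took in their host genes. Alternatives were no expression filter, a filter of 7, size thresholds of 1.5-fold, 1.25-fold and 2-fold, the mean of a gene's probe sets, the mean of a list, Spearman correlation, quantile normalization repeated over 6 arrays, loess correction of each difference (span 0.4), limma's trended robust prior, an adjusted p of 0.10 and leaving out each line. A prior from the 6-array fit, each gene's own residual, loess-corrected values in the 4-array fit, repeated quantile normalization for list medians in HCT116, and leaving out overlapping neighbours were added after seeing the data.

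Both limma fits were tested on simulated data with known changes. Over 4 arrays and 14033 genes, 2 of 49 genes changed by 0.5 (log2) were recovered, 29 of 47 changed by 1, 50 of 50 changed by 2 and 48 of 48 changed by 3, with 22 false calls among 13839. Over 6 arrays and 14335 genes the numbers were 1 of 50, 36 of 48, 50 of 50 and 48 of 48, with 9 false calls among 14139. For the list percentiles, with genes simulated as independent, 15 of 200 unchanged lists lay outside 2.5 to 97.5 and 47 of 50 lists shifted by 0.3 did. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 was used for the rest.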

Results

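Expression was measured on 6 Affymetrix arrays, 1 for each of 6 groups. HCT116 is a human colon cancer line, and HCT116-p53KO is its derivative described in the labels as lacking p53. Both were transfected with siRNA against NRF3 or with control siRNA, and RNA was taken 48 h later. H1299 is a human non-small cell lung carcinoma line, here stably expressing NRF3 or GFP from a plasmid after selection with G-418. NRF3 is the CNC-family basic leucine zipper transcription factor encoded by NFE2L3, a relative of NRF1 and NRF2. With 1 array per group no difference within a line had a replicate check, and the number of arrays limits the precision of every value. Levels are given as RMA log2 intensities and differences on the log2 scale.

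NFE2L3 was lower on both NRF3 siRNA arrays and higher on the NRF3 plasmid array, as the labels require. Its level was 8.97 with control siRNA and 6.62 with NRF3 siRNA in HCT116, which is 5.11-fold lower. In HCT116-p53KO the levels were 8.71 and 7.15, or 2.94-fold lower. In H1299 the level was 8.18 with GFP and 10.20 with NRF3, or 4.06-fold higher. Between the control siRNA arrays, NFE2L3 differed by -0.26 in HCT116-p53KO against HCT116. The paralogs differed in opposite directions after siRNA: NFE2L1, which encodes the proteasome regulator NRF1, was higher in HCT116 (0.83) and HCT116-p53KO (0.51), and NFE2L2, which encodes NRF2, was lower (-0.63 and -0.50).

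**Figure D1:**
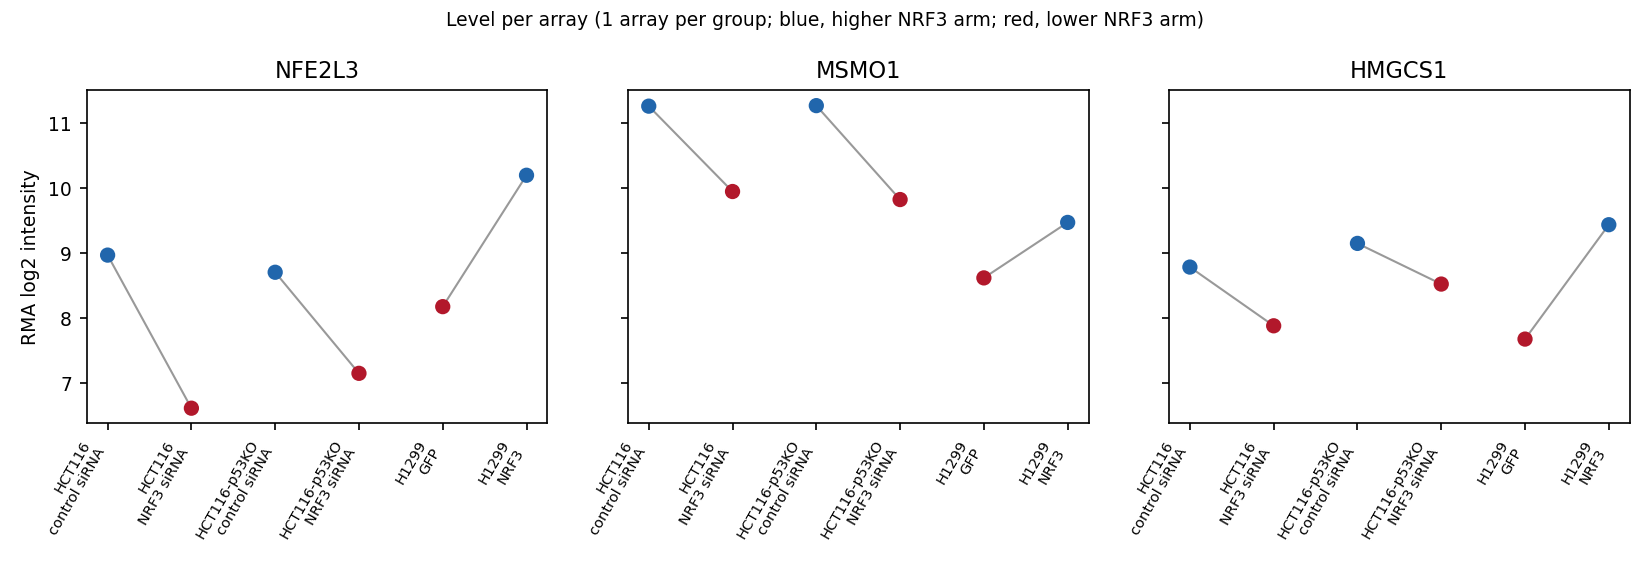
RMA log2 intensity (y axis) of NFE2L3 and of the sterol synthesis genes MSMO1 and HMGCS1 on each of the 6 arrays (x axis), with 1 point per array and a line joining the arrays compared within a cell line. Blue marks the arm with more NRF3 and red the arm with less, and each gene is higher in the blue arm of every pair, by 2.35, 1.55 and 2.02 for NFE2L3.

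The first comparison asked which transcripts differed after NRF3 knockdown in HCT116. Beside NFE2L3, the lowest genes were IFNE (-2.55), a type I interferon of epithelia, and RBMS1 (-2.21), an RNA-binding protein. LGMN (-2.10), the lysosomal protease legumain, ABHD2 (-2.05), a lipid hydrolase, SKIL (-1.93), a repressor of TGF-beta signalling, and TOMM20 (-1.89), a mitochondrial import receptor, followed. HMMR (-2.09), a spindle-associated hyaluronan receptor, OIP5 (-1.59), a centromere protein, and ADAM32 (-1.69), a member of the ADAM family, were also among the lowest. The highest were OLFM2 (1.62, or 3.07-fold), an olfactomedin, ACTA2 (2.84-fold higher), smooth muscle actin, GANAB (1.44), a glucosidase of the endoplasmic reticulum, and SETD7 (1.43), a lysine methyltransferase. RGS6 (1.38), CPA4 (1.37), SKAP1 (1.35), PLA2G7 (1.26), the long noncoding RNA LCAL1 (1.24) and CD24 (1.21), a surface glycoprotein, came next. Where an array compared lay under a log2 intensity of 6, low on the scale, the size and rank of a difference are uncertain. Here this held for IFNE, SKIL, ADAM32, RGS6, SKAP1 and LCAL1.

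Mitotic genes were lower as a group in HCT116. Of 24 measured G2 and mitosis genes, 22 were lower, 16 of them by at least 1.5-fold, and the median of -0.69 lay below those of all 10000 random lists matched on expression. CENPE (-1.21), a kinetochore motor, TTK (-1.20), a spindle checkpoint kinase, and the spindle kinesins KIF11 (-1.11) and KIF23 (-1.06) were the lowest. Cholesterol synthesis genes were also lower, 14 of 17, with a median of -0.45 that again lay below all 10000 random lists. MSMO1 (-1.31), the sterol C4-methyl oxidase, ACAT2 (-0.96), which makes acetoacetyl-CoA, HMGCS1 (-0.90), the HMG-CoA synthase, and NSDHL (-0.89), a sterol dehydrogenase, differed most. Direct p53 targets were higher, 26 of 31, with a median of 0.31 above all 10000 random lists. XPC (0.99), a DNA damage recognition factor, PLK2 (0.95), a stress-induced kinase, ABCA12 (0.83), a lipid transporter, and SESN1 (0.79), a sestrin, differed most. TP53INP1 (-0.67) and GDF15 (-0.16) were among the 5 lower, and CDKN1A was at 0.16. The sterol, p53, cell cycle and proteasome lists cover themes that published work has tied to NRF3, some of it possibly on these arrays, so their direction here and below is not independent evidence.

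NF-kappaB targets were higher in 10 of 11 members, with a median of 0.32 at percentile 99.8 and the chemokines CXCL1 (0.94) and CXCL8 (0.70) among them. ATF4 and endoplasmic reticulum stress genes had a median of 0.16 at percentile 99.6, with ASNS, asparagine synthetase, at 0.81 and ATF4 at 0.74. Interferon-stimulated genes had a median of -0.30 at percentile 0.18. IFIT1 was at -1.36 and IFIH1, an RNA sensor, at -0.62, both uncertain in size since an array lay under 6. The lists given above were the 6 of 26 whose medians lay outside the central 95% of matched random lists. At the nominal 5%, 1.3 would do so. In simulation 15 of 200 unchanged lists did, but with genes simulated as independent. Members of a real list can vary together, so chance may give more than that, by an amount the simulation cannot show. E2F and DNA replication genes lay just inside, at -0.20 and percentile 2.6.

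In HCT116, 31 genes were at least 2-fold higher and 144 at least 2-fold lower among 14034 expressed genes. This split moved to 47 and 117 when quantile normalization was repeated over the 6 arrays. RBMS1 was at -1.45 when all its probe sets were averaged, and IFNE overlaps MIR31HG, so their signals cannot be taken as separate. MIR31HG, a long noncoding RNA at -2.11, belongs among the 10 lowest in place of OIP5, but the name pattern for small RNAs had kept it out, and it was named after its value was seen.

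The same knockdown in HCT116-p53KO asked how the response looked without p53. PLA2G10 (-2.03), a secreted phospholipase, IFNE (-1.88), ITGA2 (-1.68), the integrin alpha 2 chain, and AHNAK2 (-1.65), a large scaffold protein, were the lowest. SKIL (-1.62), TP53INP1 (-1.61), a p53-inducible regulator of cell death and autophagy, ABHD2 (-1.60), LGMN (-1.46) and IFITM1 (-1.45), an interferon-induced membrane protein, followed. The highest were NETO2 (1.64), a kainate receptor partner, KIF1C (1.39), a kinesin, SETD7 (1.35), GASK1B (1.35), a Golgi-associated protein, and SERPINI1 (1.34), neuroserpin. R3HCC1 (1.34), the transcription factor MYB (1.34), GANAB (1.32), the glucosyltransferase POGLUT3 (1.21) and MTA1 (1.17), a subunit of the NuRD chromatin complex, came next. PLA2G10, IFNE, SKIL, TP53INP1 and SERPINI1 had an array under 6, so the sizes of their differences are uncertain.

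Cholesterol synthesis genes were lower in 11 of 17 members, with a median of -0.25 at percentile 0.02, and MSMO1 (-1.44), IDI1 (-0.70), the isopentenyl diphosphate isomerase, NSDHL (-0.64) and HMGCS1 (-0.63) differed most. Genes of SREBP2 regulation and cholesterol uptake had a median of -0.22 at percentile 0.41, with DAB2, an endocytic adaptor, at -0.85 and INSIG1, a sterol sensor, at -0.40. Mitotic genes were lower in 15 of 24 members with a median of only -0.13, at percentile 0.33, and none was lower by 1.5-fold. E2F and replication genes were higher in 19 of 25, with a median of 0.19 at percentile 99.3 and CCNE2, cyclin E2, at 0.64. WNT targets were lower in 12 of 14, with a median of -0.19 at percentile 0.3 and CCND1, cyclin D1, at -0.58. Antioxidant genes had a median of -0.15 at percentile 0.42, with TXNRD1, thioredoxin reductase, at -0.90 and the transporter ABCC2 at 0.90. The NRF, small MAF and BACH family, which includes NFE2L3 itself, had a median of -0.20 at percentile 1.96. In HCT116-p53KO the p53 targets were split, 15 higher and 15 lower, with a median of 0.00 at percentile 40.9, although GDF15, a stress cytokine, was at -1.18 and PLK2 at 0.66. XPC (0.57) and SESN1 (0.28), among the most different in HCT116, were higher here too, as PLK2 was, and ABCA12 lay under 6 on both arrays.

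In HCT116-p53KO, 38 genes were at least 2-fold higher and 59 at least 2-fold lower among 13680 expressed genes. At 1.5-fold the balance was reversed, with 496 higher and 325 lower. Medians lay outside the central 95% of random lists for 7 of 26 lists, against a nominal 1.3.

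The next question was which of these differences the knockdowns shared. Across 13566 genes expressed in both comparisons the log2 differences correlated with Pearson r = 0.535 and Spearman rho = 0.419, a description across genes, which are not independent replicates. At 1.5-fold or more, 228 genes were lower in both lines against 19.6 expected for independent lists, and 160 were higher in both against 12.3. Beside NFE2L3, IFNE, SKIL, ABHD2 and LGMN, the genes lowest in both lines included MSMO1, MEST (-1.44 and -1.34), an imprinted hydrolase, APOBEC3B (-1.41 and -1.33), a cytidine deaminase, TIMP2 (-1.26 and -1.33), a metalloproteinase inhibitor, and the pseudogene ANKRD36BP1 (-1.26 and -1.30). ANKRD36BP1 overlaps SFT2D2 (-1.12 and -1.14, named after its values were seen), so these signals cannot be taken as separate either. Those highest in both, beside GANAB, SETD7, KIF1C and MTA1, included ACAT1 (1.20 and 1.01), the mitochondrial acetoacetyl-CoA thiolase, PFKL (1.08 and 1.04), the liver phosphofructokinase, and ENSA (1.06 and 1.06), a phosphatase inhibitor. GRAMD2A (1.02 and 1.01), TMEM141 (1.02 and 0.98) and ZDHHC16 (0.97 and 1.08), a palmitoyltransferase, were also among them.

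limma with cell line as a block over these 4 arrays called 1398 of 14148 genes at an adjusted p of 0.05, of which 768 fell and 630 rose with NRF3 siRNA. The difference went the same way in both lines for 1382 of them. With a common SE a call was a cut on the mean of both differences, at 0.455 (1.37-fold) or more. Opposite signs could pass only with a far larger difference in 1 line, so this agreement follows largely from the selection. Of 17 cholesterol synthesis genes, 7 fell over all genes tested: MSMO1 by 1.38, HMGCS1 and NSDHL by 0.76, SC5D by 0.75, ACAT2 by 0.73, IDI1 by 0.72 and LSS by 0.60, each ± 0.16 (SE). Adjusted over the list alone, 8 fell and 1 rose, TM7SF2, a sterol reductase. Of 24 mitotic genes 8 were called lower over all genes and 14 adjusted over the list alone, calls carried chiefly by HCT116: in HCT116-p53KO the 8 lay between -0.35 and 0.04, with CENPE at 0.04, TTK at -0.15 and KIF23 at -0.14. Of 31 p53 targets 5 rose and 2 fell, or 7 and 3 adjusted over the list alone. HSPE1, a mitochondrial co-chaperonin, fell by 1.11 and DNAJB1, a cytosolic co-chaperone, by 0.82. With 1 residual degree of freedom limma pooled the spread fully over genes. With the prior of the fit of all 6 arrays in its place it called 0 genes (1822 at an unadjusted p of 0.05), with each gene's own residual 3, and on loess-corrected values 582.

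Where the lines differed, it was chiefly in cell cycle, p53 and NF-kappaB genes. The siRNA difference in HCT116 minus that in HCT116-p53KO had a median of -0.54 for mitotic genes and -0.34 for E2F genes, both below all 10000 matched random lists. It was 0.29 for p53 targets, 0.55 for NF-kappaB targets and 0.14 for ATF4 and stress genes, all above all 10000 lists, and 0.21 at percentile 99.96 for WNT targets. Antioxidant genes (0.06, percentile 99.4), autophagy and lysosome genes (0.06, percentile 99.2) and 20S proteasome subunits (-0.23, percentile 1.85) also lay outside the central 95%. After loess correction antioxidant genes lay inside it (0.09, percentile 95.2), and mesenchymal and matrix genes, at 0.19 and percentile 96.7 before, lay outside (0.21, percentile 99.3). Cholesterol synthesis genes lay inside, at -0.20 and percentile 9.63. No test of the difference between the lines across replicates could be made with 1 array per group.

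**Figure D2:**
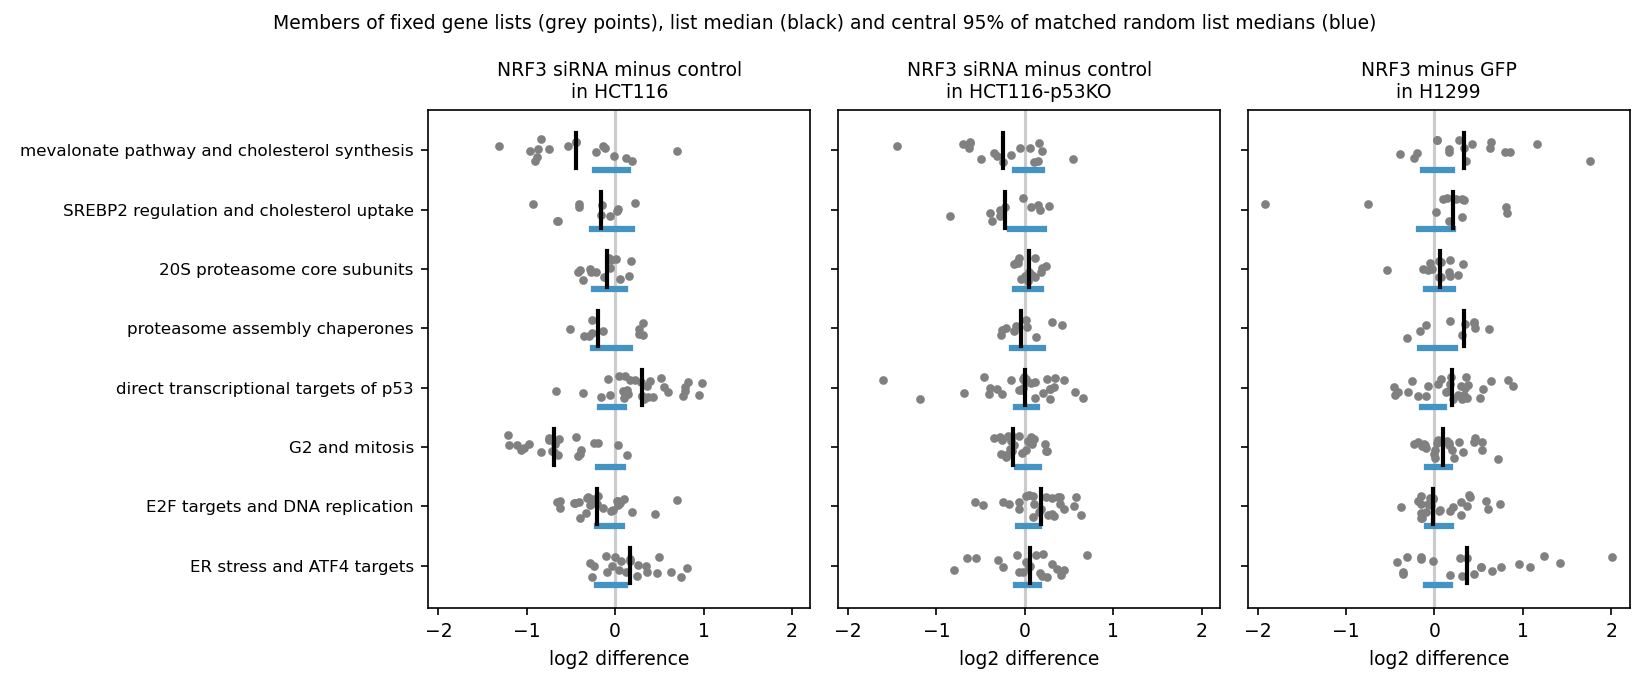
Log2 differences (x axis) of the measured members of 8 gene lists (y axis) in the 3 NRF3 comparisons, with each grey point a gene, the black bar the list median and the blue bar the central 95% of medians of 10000 expression-matched random lists. The cholesterol synthesis median lies below the blue bar in both siRNA panels (-0.45 and -0.25) and above it in H1299 (0.34), while the mitotic median of -0.69 in HCT116 has no counterpart of that size in the other panels.

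Overexpression in H1299 asked which transcripts differed when NRF3 was raised in a line of another tissue. The largest difference was in SPP1, the secreted phosphoprotein osteopontin, at -5.48. APOBEC3C (-3.36), a cytidine deaminase, EMP2 (-3.03), a tetraspan membrane protein, ZDHHC15 (-2.90), a palmitoyltransferase, TSPYL5 (-2.76), ZMAT1 (-2.71), GATM (-2.66), which acts in creatine synthesis, PCDHB2 (-2.58), a protocadherin, PTPRS (-2.20), a receptor phosphatase, and RTL6 (-2.20) followed. The highest were ANKRD1 (4.35), an ankyrin repeat protein and YAP target, MYPN (3.79), a sarcomeric protein, ANXA3 (3.25), an annexin, and the pseudogene ZNF542P (3.07). PDLIM1 (2.63), a cytoskeletal adaptor, LINC00417 (2.47), DKK1 (2.43), a WNT antagonist, S100A16 (2.11), a calcium-binding protein, and DDIT4 (2.01), an inhibitor of mTORC1, came next beside NFE2L3. Of these 20 genes 15 had an array under 6, all but APOBEC3C, TSPYL5, ZNF542P, S100A16 and NFE2L3. The sizes of those 15 differences, that of SPP1 included, and the order are uncertain.

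Cholesterol synthesis genes were higher in 14 of 17 members in H1299, 6 of them by at least 1.5-fold, with a median of 0.34 at percentile 99.96. HMGCS1 (1.76), SC5D (1.16), the sterol C5-desaturase, MSMO1 (0.85) and ACAT2 (0.80) differed most. Genes of SREBP2 regulation and cholesterol uptake had a median of 0.20 at percentile 96.9, with 10 of 12 higher and INSIG1 at 0.81. DAB2, lower after siRNA, was lower here too, at -1.92, with an array under 6. ATF4 and stress genes were higher in 14 of 21 with a median of 0.37 above all 10000 random lists, led by DDIT4, CHAC1 (1.42), a glutathione-degrading enzyme, ASNS (1.24) and MTHFD2 (1.08), a mitochondrial folate enzyme. Proteasome assembly chaperones had a median of 0.33 at percentile 99.6, with PSMG4 at 0.62 and POMP, the 20S maturation factor, at 0.44. The p53 target list was higher in 20 of 28, with a median of 0.20 at percentile 99.9, and PLK3 (0.89) and SESN2 (0.84) differed most. Mitotic genes had a median of 0.09 at percentile 76.8. Autophagy and lysosome genes had a median of -0.13 at percentile 1.81, with the cathepsins CTSL (-1.20) and CTSB (-0.82) the lowest. In the antioxidant list, with a median of 0.02 at percentile 53.8, the cystine transporter SLC7A11 was at 1.80 and TXNRD1 at 1.10. Among genes of cholesterol efflux, with a median of -0.15 at percentile 14.9, the exporter ABCA1 was at -1.38.

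In H1299, 77 genes were at least 2-fold higher and 129 at least 2-fold lower among 11304 expressed genes, and 5 of 24 lists lay outside the central 95%, against a nominal 1.2. The number lower was 81 when genes had to reach a log2 intensity of 7. At 1.5-fold the balance was reversed here as well, with 545 higher and 475 lower.

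Proteasome core subunits had medians inside the central 95% in each NRF3 comparison, although the siRNA differences of the lines parted as given above. The medians were -0.10 in HCT116, 0.05 in HCT116-p53KO and 0.06 in H1299, at percentiles 32.6, 57.6 and 56.6, and none of the 14 was 1.5-fold higher or lower. The 19S regulatory subunits had medians of -0.14, 0.05 and 0.19, the last with 15 of 16 members higher and at percentile 96.3. Immunoproteasome and PA28 genes had medians of 0.14, 0.05 and 0.16, and assembly chaperones had -0.20 and -0.04 after siRNA.

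Other lists stayed within the central 95% in all 3 NRF3 comparisons wherever 5 or more members were measured. In the same order of lines, medians were -0.03, 0.09 and -0.00 for fatty acid synthesis, where SCD, the stearoyl-CoA desaturase, was at -0.89 and -0.57 after siRNA. They were -0.17, -0.06 and -0.05 for endocytosis and macropinocytosis, and -0.19, 0.03 and 0.04 for heat shock proteins. For hypoxia and glycolysis they were -0.09, -0.09 and 0.15, and for mesenchymal and matrix genes -0.01, -0.10 and -0.06. Ribosomal proteins had 0.04, 0.14 and 0.04, and cholesterol efflux genes 0.04 and -0.11 after siRNA. Markers of colon epithelium had medians of 0.01, -0.10 and 0.04. Lung and neuroendocrine markers had 0.20, -0.12 and -0.11, fibroblast markers 0.25, -0.09 and -0.02, and leukocyte and erythroid markers 0.23, -0.46 and -0.43, the last list over at most 4 measured genes. Mean and median differed in sign for cholesterol efflux, WNT and colon genes in HCT116, for cholesterol efflux, endocytosis, heat shock, interferon and p53 target genes in HCT116-p53KO, and for fatty acid, endocytosis, E2F, interferon and matrix genes in H1299.

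Knockdown and overexpression were then set side by side, with every difference taken as more NRF3 minus less. At 1.5-fold or more, 19 genes were higher with NRF3 in all 3 lines and 10 were lower. If the set shared by the siRNA comparisons were independent of H1299, 9.57 and 5.23 would be expected. Beside NFE2L3, the most uniform genes higher with NRF3 included RMND5A (1.35, 1.07 and 0.98), a ubiquitin ligase subunit, MSMO1 (1.31, 1.44 and 0.85) and DDAH1 (1.15, 0.85 and 0.81), which degrades methylated arginines. HMGCS1, IDI1 and SC5D were also among the 19. Lower with NRF3 were SLC16A9 (-0.93, -1.06 and -1.22), a carnitine transporter, CC2D2A, a ciliary protein, BFSP1, a lens filament protein, SUMF2, a sulfatase-modifying factor relative, and SEMA3A, an axon guidance factor, with SLC16A9 and SEMA3A under 6 on an array. Of the genes near the top of both siRNA comparisons and expressed in H1299, some were near 0 there, such as SKIL (0.12), LGMN (0.05), ABHD2 (-0.14), GANAB (0.08) and SETD7 (0.23). Others differed more, in either direction, such as MEST (-0.67), KIF1C (0.47), PFKL (-0.43) and ACAT1 (0.42).

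limma over all 6 arrays with line as a block called 1 of 14492 genes, NFE2L3, at 1.98 ± 0.17 (SE) with an adjusted p of 0.0401, higher with more NRF3 in 3 of 3 lines. At an unadjusted p of 0.05 there were 1615, against 1281 when the H1299 pair was reversed. This count is therefore no measure of an effect shared by 3 lines. Adjusted over the list alone, 8 of 17 cholesterol synthesis genes rose with NRF3, namely MSMO1 by 1.20, HMGCS1 by 1.10, SC5D by 0.88, ACAT2 by 0.75, IDI1 by 0.69, NSDHL by 0.52, LSS by 0.51 and DHCR7 by 0.44, and TM7SF2 fell by 0.43. Over the whole gene set none of them passed. NSDHL was at 0.03 in H1299, so its value here was carried by the siRNA pairs. Of the 24 mitotic genes and 31 p53 targets 0 passed, even adjusted over the list alone. Adjusted over its own list, BNIP3, a mitophagy receptor, rose by 0.74 and PTGS2, cyclooxygenase-2, and ME1, malic enzyme, fell by 0.66 and 0.58. NFE2L2 rose by 0.45 and NFE2L1 fell by 0.51 in the same way. PTGS2 lay under a log2 intensity of 6 on both H1299 arrays, near the floor, so its difference there is uncertain. Across genes, knockdown in HCT116 correlated with overexpression at r = 0.0896 and knockdown in HCT116-p53KO at r = 0.0300. Without the HCT116 pair or without the HCT116-p53KO pair limma called 0 genes, and without the H1299 pair 1398.

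**Figure D3:**
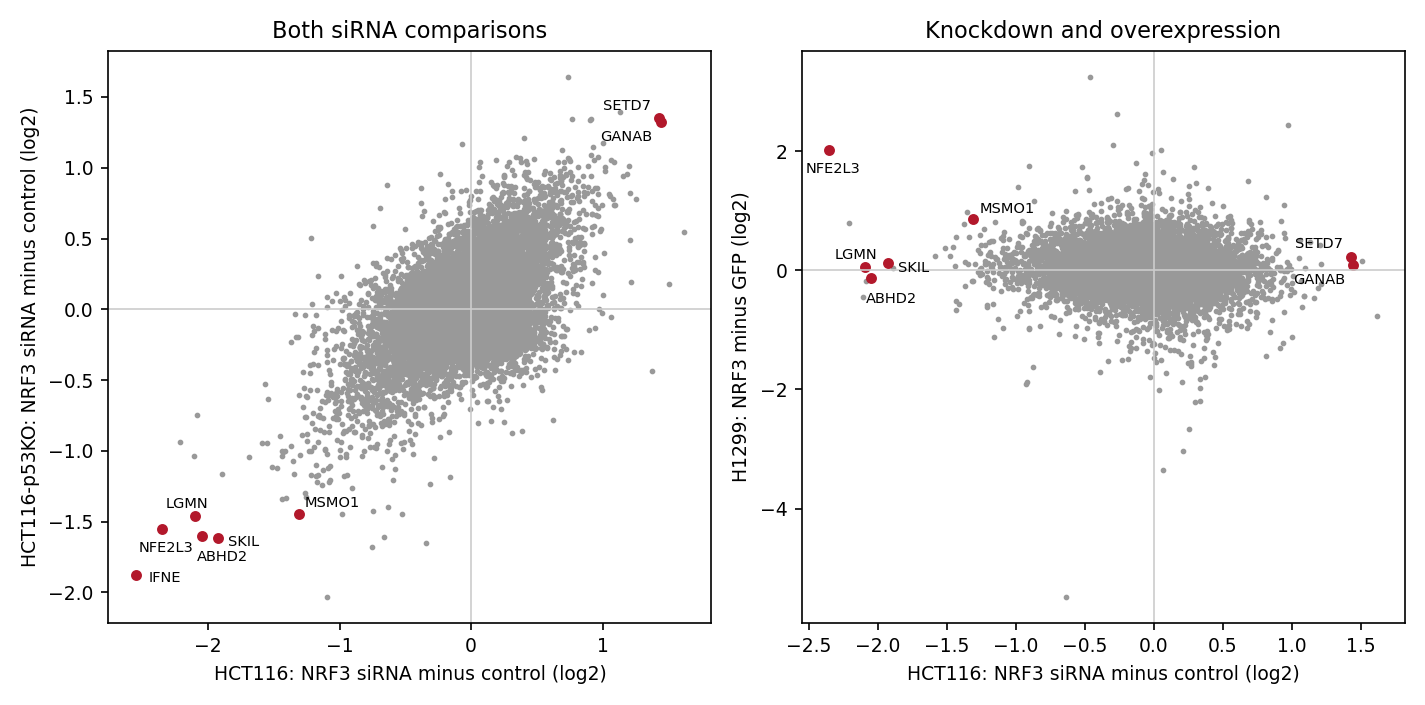
Log2 difference of each expressed gene (grey points) after NRF3 siRNA in HCT116 (x axis) against that after NRF3 siRNA in HCT116-p53KO (left, y axis) and with NRF3 overexpression in H1299 (right, y axis), with named genes in red. The siRNA differences follow each other (r = 0.535). Knockdown and overexpression hardly do (r = 0.0896 with both taken as more NRF3 minus less, and of opposite sign on the axes drawn), and there SKIL, LGMN, ABHD2, GANAB and SETD7 lie near 0 and NFE2L3 and MSMO1 are lower after siRNA and higher with overexpression.

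The control siRNA arrays of the HCT116 lines were compared to describe the background on which the knockdowns were made. Direct p53 targets were lower in HCT116-p53KO in 28 of 31 members, with a median of -0.44 below all 10000 random lists, led by GDF15 (-2.35), FAS (-1.84), a death receptor, TP53INP1 (-1.39) and SESN1 (-1.25). Interferon-stimulated genes were lower in 11 of 13, with a median of -0.42 below all 10000 lists. IFIH1 was at -1.18, uncertain in size since an array lay under 6. This comparison and the HCT116 knockdown share the HCT116 control siRNA array. Interferon genes were lower than on that array in both, and ATF4 and stress genes were higher in both (medians of 0.16 after siRNA and 0.21 here). For these lists, 1 deviating array and 2 separate differences cannot be told apart. IFIT1 was at 6.65 on the shared array and at 5.29, 5.81 and 5.85 on the other HCT116-family arrays. The lowest genes were NRIP1 (-4.73), a nuclear receptor corepressor, PROM1 (-4.04), a membrane glycoprotein, EHF (-3.65), an epithelial ETS factor, VSNL1 (-3.28), a calcium sensor, and TRIM38 (-3.20). The highest were TENM3 (3.69), a teneurin, SYTL2 (2.76), a RAB27 effector, ANXA10 (2.42), an annexin, NR5A2 (2.11), a nuclear receptor, and CSMD3 (2.01). All of these 10 but VSNL1, SYTL2 and NR5A2 had an array under 6, so the sizes of the other 7 differences and the order are uncertain.

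Stress genes (0.21, above all 10000 lists), E2F genes (0.17, percentile 99.98) and hypoxia genes (0.17, percentile 99.97) were higher in HCT116-p53KO. The mean of the hypoxia list was -0.04, opposite to its median, with SLC2A1, a glucose transporter, at -2.10. Mean and median also differed in sign for WNT targets and for the NRF, small MAF and BACH family. Antioxidant genes (-0.13), ribosomal proteins (-0.08), immunoproteasome genes (-0.20), colon epithelium markers (-0.13), cholesterol efflux genes (-0.20) and fatty acid genes (-0.08) were lower, at percentiles 0.21, 0.345, 0.47, 1.58, 2.3 and 2.26. Cholesterol synthesis genes had a median of -0.01 and mitotic genes of 0.05, both within the central 95%. In all, 27 genes were at least 2-fold higher and 180 at least 2-fold lower among 13827, and 11 of 26 lists lay outside that range, against a nominal 1.3. With 1 array of each line, loss of p53 and any other difference between the lines cannot be told apart.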

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

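The tests of p53 targets, of the shared differences after loess correction and of their correlation by intensity were chosen only after results had been seen; the others were set before.

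After NRF3 siRNA, 3 gene lists had medians of opposite sign in the HCT116 lines with a difference outside the central 95% of matched random lists. The difference was not tested across replicates. The median of the gene-wise difference, HCT116 minus HCT116-p53KO, was -0.23 for 20S proteasome subunits, -0.34 for E2F and DNA replication genes and 0.55 for NF-kappaB targets. After loess correction these were -0.13, -0.23 and 0.48.

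Probe sets without a single gene name, which entered no comparison of genes, also differed by at least 2-fold. There were 253 in HCT116 (3.22% of those expressed, against 1.2% of named genes), 88 in HCT116-p53KO (1.12% against 0.709%) and 119 in H1299 (2.05% against 1.82%).

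Mitotic genes were lower after NRF3 siRNA in HCT116 than in HCT116-p53KO, by a median of -0.54. An intensity-dependent bias between arrays is argued against as the whole cause, since the median after loess correction of both differences was -0.44, still below all 10000 matched random lists. A p53 response in the line that carries p53 is a candidate explanation. The p53 targets lay at percentile 100 of matched lists for the same difference between lines, with a median of 0.29. The list's medians (0.31 and 0.00) had already been seen, so this outcome was nearly fixed in advance and adds little support. The difference also drew on the 15 of 30 targets lower after siRNA in HCT116-p53KO, such as TP53INP1 (-1.61), GDF15 (-1.18) and CDKN1A (-0.69). That line is described as lacking p53. The percentile does not show that p53 acted on the mitotic genes. The list was also higher with NRF3 in H1299 (0.20, percentile 99.9) and so is not particular to NRF3 loss with p53. Knockdown that was deeper in HCT116 (5.11-fold against 2.94-fold) stays open and untested. With 1 array per group the hypothesis rests on 4 arrays.

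Differences shared by both siRNA comparisons were many, with r = 0.535 across genes, and an intensity-dependent bias between arrays is argued against as the whole cause, since r was 0.567 after loess correction. Other technical variation across whole arrays shared by the NRF3 siRNA arrays stays open. It had been predicted to appear also in the 4269 genes under a log2 intensity of 6 on all 4 arrays, where r was 0.0186, but these lie near the floor and r rose steadily with intensity, from 0.151 at 6 to 7 to 0.769 at 10 or more, so their low r excludes nothing. The siRNA acting on transcripts other than that of NFE2L3 stays open too: of 206 genes lower in both lines by 1.5-fold and measured in H1299, 55.8% were higher with NRF3 there, and of 143 higher in both, 49.0% were lower there, at percentiles 86.7 and 52.4 of matched random sets, and a response to NRF3 that differs between tissues predicts the same. SKIL, LGMN, ABHD2, GANAB and SETD7, near 0 in H1299, may belong to either kind. The cholesterol synthesis list was mirrored there in its median, with 14 of 17 members higher, but NSDHL was at 0.03. The separate derivation of the stable lines cannot be parted from NRF3 there.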

How the results depend on the processing

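Of the recomputed values that answer a comparison, 498 stayed within the limits set, 35 moved and 1 list median outside the central 95% of random lists changed sign, and the cause was not tested except where the setting itself (a lower size threshold, fewer genes or arrays) gives it. Medians inside the central 95% were not counted as changing sign, although several did, as a mean or under another setting. Cell line was the block in both limma fits, which pairs the arrays of a line. At 1.5-fold, genes higher and lower numbered 381 and 845 in HCT116, 496 and 325 in HCT116-p53KO, 545 and 475 in H1299, and 120 and 477 between control arrays. Repeated quantile normalization gave 47 higher in HCT116 (31 otherwise), and a filter of 7 gave 81 lower in H1299 (129). As a mean in place of a median, hypoxia genes in HCT116-p53KO against HCT116 changed sign to -0.0355, SREBP2 regulation and uptake in H1299 went from 0.20 to 0.0495 and p53 targets after siRNA in HCT116-p53KO from 0.00 to -0.0551. Loess correction moved endocytosis genes in H1299 to -0.0866. The correlation of both knockdowns was 0.424 without a filter, 0.624 with a filter of 7, 0.567 after loess and 0.419 by Spearman. That of HCT116 with H1299 was 0.0609 without a filter and 0.0630 after loess, and that of HCT116-p53KO with H1299 was 0.00633 by Spearman.

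The 1398 genes of the 4-array limma fit became 0 with the prior of the 6-array fit, 3 with each gene's own residual and 582 after loess, all chosen after seeing the data; the trended prior gave 1845. The 1 gene of the 6-array fit ranged from 0 without HCT116 or HCT116-p53KO to 1398 without H1299, where limma again pooled the spread fully over genes. Shared by both knockdowns were 35 lower and 8 higher at 2-fold and 781 and 732 at the lowest threshold tried (228 and 160 at 1.5-fold). In all 3 comparisons 1 and 0 genes moved with and against NRF3 at 2-fold and 121 and 123 at the lowest, and 6 moved against it with a filter of 7 (10 otherwise). Of NFE2L3 and the genes named as largest in a comparison, recomputed after loess and over all probe sets, only RBMS1 in HCT116 moved, to -1.45 over all its probe sets. Other named genes were not recomputed singly. Signal over background limits which genes could be compared, and fewer reached the filter in H1299, whose arrays lie lower on the scale.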

Other observations

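Leaving out overlapping neighbours was chosen only after results had been seen. The other tests below were set before, and the YAP and TAZ list was written after ANKRD1, CCN1 and CCN2 had been seen.

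In H1299 with NRF3, 3 familiar targets of YAP and TAZ, the transcription cofactors of the Hippo pathway, were at least 2-fold higher. ANKRD1 was at 4.35, uncertain in size since its level on the GFP array was low. CCN2, a matricellular growth factor, was at 1.62 and CCN1, its relative, 2.82-fold higher. The hypothesis that a wider YAP and TAZ programme was higher was tested on 17 other targets, whose median was 0.33 at percentile 99.96 of matched random lists, with 13 higher and TGFB2, CRIM1 and NUAK2 the highest. After siRNA the same list had medians of -0.00 in HCT116 and -0.07 in HCT116-p53KO, at percentiles 48.9 and 13.8, while CCN1 was 0.68 higher in HCT116, and the difference between the pairs was not tested. The higher values in H1299 may follow NRF3 or the separate derivation of the stable lines, and 1 array per group cannot part these.

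Genes at least 2-fold different tended to lie side by side on chromosomes. Leaving out neighbours with related symbols, 12 neighbouring pairs moved the same way in HCT116-p53KO against HCT116, such as DPP4 with IFIH1 and IFIH1 with GCA, against 2.22 in permuted gene orders. In H1299 there were 11, such as GALNT14 with EHD3, against 1.88. Cross-hybridisation among related neighbours is argued against, since the one-sided permutation p without them was 0.0001, the smallest the permutations can give. Regional differences between separately derived cell populations, such as copy number, stay open: the ratio to the permuted number was 5.41 and 5.84 in those pairs against 4.22 and 8.93 in the siRNA comparisons, and without overlapping genes, which made up 3 of 6 and 2 of 3 siRNA pairs, 5.52 and 5.26 against 2.35 and 3.31, the last from 1 pair, with 95% Poisson intervals that overlap (2.75 to 9.87 and 2.40 to 9.98 against 0.484 to 6.86 and 0.0838 to 18.4).

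The fit across 3 lines called 1 gene, NFE2L3. Of the 10 splits of the 6 arrays into equal groups, 3 gave at least 1 gene and the highest other count was 10, in splits that parted 1 of the 3 pairs. The other splits that part all 3 pairs gave 0 genes. At an unadjusted limma p of 0.05 they gave 1281, 152 and 204, against 1615 for the real split. The 1281 came with only the H1299 pair reversed. In any case 10 splits are too few for a share under 0.05.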
